A study of Mus musculus with 6 samples.

How the data were processed

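Poly(A) RNA from BCR-ABL-transformed mouse pro-B cells was sequenced in 6 libraries, 1 for each of 3 Ikaros genotypes at each of 2 days of culture. Per the labels' protocols, the RNA was enriched with a poly(A) purification kit and made into fragmented double-stranded cDNA for Illumina sequencing, and no strand-marking step is named. Reads from a gene and from an overlapping antisense gene were therefore taken as not distinguishable. Per the submitters' processing notes, TopHat and bedtools were used with the mouse build mm9, and the notes name no versions. The annotation release and the read numbers were not given in the sources used here.

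The authors deposited 1 table of RPKM values (reads scaled to transcript length and to the mapped reads of the library), with 26531 RefSeq transcript rows and a transcript length for each row. The deposited RPKM values are rounded to 1 decimal, so the smallest value above 0 is 0.1, and which reads the scaling used is not given in the sources used here. A stray entry (1 row) without a gene name was left out. The depth of the libraries is unknown. Low values of rows shorter than 160 bases were checked for steps that would mark single reads. At the best of the depths tried, between 43.0% and 57.0% of them fell on such steps, against 40.1% to 51.3% by chance, so no depth was recovered and no counting interval can be given. The 22098 symbols include 3305 with several rows, and the row with the highest mean over the 6 libraries stood for each. The reference tables at hand are of another mouse build than the values, so no coordinates are given.

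The values were transformed as log2(RPKM + 1), with a pseudocount of 1, and a gene was tested when it reached an RPKM of at least 1 in at least 2 of the 6 libraries, which left 11379 genes. A fold change on this scale understates the change of low genes. The limma package (version 3.58.1, R 4.3.3) fitted genotype and day as additive terms to all 6 libraries, with empirical Bayes moderation and a mean-variance trend. The 2 residual degrees of freedom per gene were joined by a prior of 3.22. Genes were called at a Benjamini-Hochberg adjusted p below 0.05, separately for each mutant against wild type, for the ZnF4 mutant against the ZnF1 mutant, and for day 28 against day 21. A second criterion without a test counted genes at least 2-fold apart in the same direction on both days. The labels do not say whether the day 21 and day 28 libraries of a genotype came from separate cultures, so a p-value measures only how repeatable a difference was between the days, and any feature of a single culture cannot be separated from its genotype. Whether a genotype effect changed with the day could not be tested with 1 library per genotype and day.

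The replicate number of a library is its day, which the labels give, so day was kept as a block. The changes from day 21 to day 28 correlated across genes between each pair of genotypes, with Pearson coefficients of 0.433, 0.249 and 0.226. Genes are not independent replicates. No 2 libraries held the same values: the largest share of tested genes with identical RPKM in a pair was 5.61%.

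Before the data were examined, 24 gene lists with 400 entries were written, of which 399 matched a symbol. The 22 lists with at least 3 tested genes were tested against all other tested genes with limma's camera, with a preset correlation between genes of 0.01 and, beside it, an estimated correlation, and adjusted over the lists within a comparison. With the preset correlation 28 list tests over the 3 genotype comparisons passed, and with the estimated correlation 0 passed. The erythroid and mast cell lists had 1 tested gene each (Pf4, at most 79.2 RPKM, and Cpa3, at most 3.4 RPKM) and were not tested. The lists of haematopoietic zinc finger factors, V(D)J recombination, stem and early progenitor genes, Notch, restraint of energy supply, T cells, natural killer and dendritic cells, immediate early genes and sex-linked transcripts passed in none of the comparisons. Further lists, of macrophage, B-lineage restricted, hypoxia, imprinted, aminoacyl-tRNA synthetase, cholesterol synthesis, ribosomal protein and Hox genes, were written after the leading genes had been seen.

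The genes named were chosen by a rule written before the data were examined. It takes, per comparison and direction, the 10 called genes with the largest log2 difference among those 2-fold apart on both days, up to 4 members of each described list with the smallest p, and a fixed set in any case (among them Ikzf1, Ikzf3, Kit, Igll1, Vpreb1, Pax5, Ebf1, Rag1 and Il7r). Some genes that the rule names are not reported here. Genes without a described function were passed over. Where no gene was called, the places went to the genes with the largest difference in the genotype that differed least. Other genes are said to have been chosen after their values were seen.

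The steps were tested on simulated data for the ZnF1 mutant against wild type, with the spread of the 11379 real genes, 200 changed genes and 20 simulations. Of genes changed by 1 on the log2 scale 84.0% were called, and of those changed by 2, 98.4%. The second criterion found 25.6% and 99.4% of them. On average 10.0 unchanged genes were called. A list of 20 genes shifted by 0.5 had an unadjusted p below 0.05 in 20 of 20 simulations with either correlation, and an unshifted list in 0. The simulated genes varied independently, so this does not show how either correlation setting performs on genes that vary together. For the overlap of the mutants, 100 simulations of unchanged mutants shared the same wild type libraries.

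Alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.5, no filter, a mean RPKM of at least 4, median-of-ratios and quantile scaling, no variance trend, a robust variance model, no day block, every transcript row tested on its own, and each library left out in turn. Added after the data were seen were a fit without the libraries of the genotype not compared, a fit without rows under 300 bases and non-coding rows, and a fit with each library's trend over transcript length removed. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.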

Results

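Poly(A) RNA was sequenced from mouse pro-B acute lymphoblastic leukaemia cells, made by transducing C57BL/6 bone marrow with a retrovirus that carries BCR-ABL p185 and a YFP reporter. BCR-ABL is the fusion tyrosine kinase of Philadelphia chromosome-positive leukaemia. The marrow was wild type or carried a mutation of Ikaros (Ikzf1), a zinc finger transcription factor of lymphocyte development and a tumour suppressor in this leukaemia. The mutants lacked either the first or the fourth zinc finger of its DNA-binding domain and are called ZnF1 mutant and ZnF4 mutant. The comparison asks what the individual fingers contribute to gene expression in the transformed cells. Each of the 3 genotypes was sampled at day 21 and day 28 of culture, with 1 library per genotype and day and thus n = 2 per genotype. Values are RPKM as deposited. The read depth is unknown, and between 10401 and 11233 of 22098 gene symbols reached 1 RPKM in a library. Differences below are on the log2(RPKM + 1) scale with their standard error, from limma fitted to all 6 libraries, and "called" means an adjusted p below 0.05 in that fit.

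The libraries grouped by genotype. Across genes, the 2 days of a genotype correlated at 0.987 to 0.992, and libraries of different genotypes at 0.903 to 0.955. The first principal component held 62.1% of the variance and set the mutants at opposite ends. The ZnF1 libraries scored 44.9 and 43.2 on it, wild type -6.6 and -13.5, and the ZnF4 libraries -34.2 and -33.8. The second held 27.8% and set wild type apart. The targeted gene, Ikzf1, had 89.2 and 78.7 RPKM in wild type at day 21 and day 28, 108 and 91.4 in the ZnF1 mutant, and 186 and 165.9 in the ZnF4 mutant. It was higher by 1.06 ± 0.07 in the ZnF4 mutant (adjusted p = 0.00129). In the ZnF1 mutant it was higher by 0.24 ± 0.07 (adjusted p = 0.0426), a call lost without the block on day and without any 1 of the wild type or ZnF1 libraries (adjusted p up to 0.272). The values cover whole transcripts, so they cannot check the loss of a single finger. Ikzf3 (Aiolos), a related factor, was lower in both mutants, with -0.49 ± 0.08 in the ZnF1 mutant and -0.51 ± 0.08 in the ZnF4 mutant. The first call was lost without either wild type library or the ZnF1 library of day 21 (adjusted p up to 0.107). The second was lost without any 1 of the wild type or ZnF4 libraries (adjusted p up to 0.162). Over the 6 libraries Igll1 (the λ5 surrogate light chain) had 663 to 1124.8 RPKM and Ebf1, a B-lineage transcription factor, 166.1 to 215.6 RPKM.

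**Figure D1:**
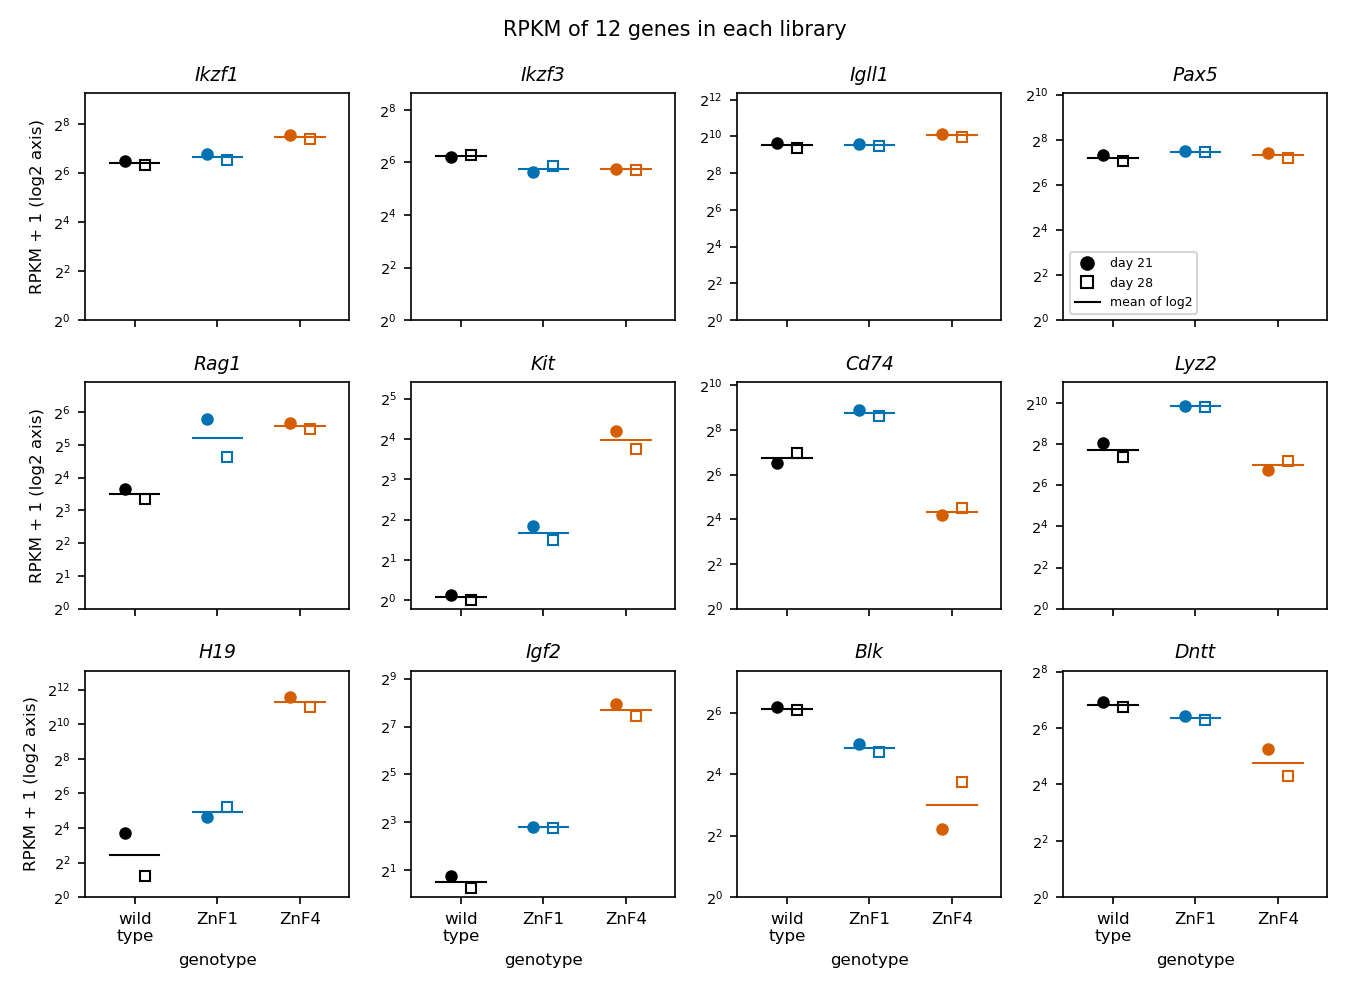
RPKM + 1 of 12 genes on log2 axes, 1 panel per gene and 3 genotypes per panel; circles are day 21, squares are day 28 and lines are means of the log2 values (n = 2). Ikzf1 reached 186 RPKM in the ZnF4 mutant, Kit was at 0.1 RPKM or below in wild type, and H19 was above 2000 RPKM in the ZnF4 mutant alone.

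In the ZnF1 mutant, macrophage and stromal transcripts were several times higher than in wild type, and replication and mitosis transcripts were lower. Of the 14 tested myeloid markers 13 were higher (13 adjusted over the list alone), with a median difference of 2.135. They included Fcgr3 (2.20 ± 0.14), Cd14 (2.37 ± 0.17) and Itgam (2.16 ± 0.15). The camera test gave an adjusted p = 6.66e-07, and adjusted p = 0.472 with an estimated correlation. All 15 tested stromal and endothelial markers were higher (15 adjusted over the list alone; median 1.70; adjusted p = 4.89e-08, and adjusted p = 0.472 with an estimated correlation), among them the chemokine Cxcl12 (2.36 ± 0.10), the proteoglycan Bgn (2.51 ± 0.12) and Col1a1 (1.70 ± 0.10). Interferon-stimulated genes were higher in 12 of 16 cases (13 adjusted over the list alone), with a median of 0.88, for example Oas2 (1.46 ± 0.14) and Oasl2 (1.58 ± 0.21). That list passed at adjusted p = 0.000159, and had adjusted p = 0.579 with an estimated correlation. Macrophages express many of these genes too.

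Of 21 tested genes of later B cell maturation, 14 were higher and 1 was lower (15 and 1 adjusted over the list alone; median 0.94; adjusted p = 0.000177, and adjusted p = 0.472 with an estimated correlation). The members with the smallest p act in antigen presentation and co-stimulation, which macrophages share: Cd86 (1.86 ± 0.10), H2-Aa (2.50 ± 0.22) and Cd74, the MHC class II invariant chain (2.03 ± 0.18). Integrin and adhesion genes were higher in 13 of 22 cases and lower in 1 (14 and 2 adjusted over the list alone; median 0.79). They included Actn1 (2.41 ± 0.10), Ctnnd1 (1.14 ± 0.07) and the focal adhesion kinase gene Ptk2 (1.82 ± 0.13). The list passed at adjusted p = 0.000113, with adjusted p = 0.472 with an estimated correlation.

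Proliferation genes were lower in 22 of 24 cases (23 adjusted over the list alone), with a median of -0.52. They included Ccne1 (-0.66 ± 0.07), Mki67 (-0.63 ± 0.08) and Mcm5 (-0.52 ± 0.07). The call of Mki67 was lost without either wild type library or the ZnF1 library of day 21 (adjusted p up to 0.0741). That of Mcm5 was lost without any 1 of the wild type or ZnF1 libraries (adjusted p up to 0.0773). The list passed at adjusted p = 2.44e-08, and had adjusted p = 0.472 with an estimated correlation. Glycolysis genes also passed (5 of 15 lower, 1 higher; 9 and 1 adjusted over the list alone). Their median was -0.31, with adjusted p = 0.0115, and adjusted p = 0.595 with an estimated correlation. Of subunits of the NuRD chromatin remodelling complex, an Ikaros partner, 6 of 13 were lower and 1 higher, the same numbers adjusted over the list alone. Their median was -0.24, with adjusted p = 0.0115, and adjusted p = 0.472 with an estimated correlation. The NuRD call was lost with quantile scaling (median -0.14; adjusted p = 0.252) and without the wild type library of day 21 (adjusted p = 0.0537). Cyclin-dependent kinase inhibitors and D cyclins did not pass as a list (2 of 10 higher, 0 lower, the same numbers adjusted over the list alone; adjusted p = 0.403). Ccnd1, which encodes cyclin D1, was higher by 2.82 ± 0.09.

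The pre-B cell receptor list did not pass (3 of 19 higher, 1 lower, the same numbers adjusted over the list alone; median -0.01; adjusted p = 0.992). Igll1 (-0.01 ± 0.11), Vpreb1 (-0.12 ± 0.17), Pax5 (0.27 ± 0.09) and Ebf1 (-0.26 ± 0.09) were not called. The V(D)J recombination list did not pass either (3 of 12 higher, 4 lower, the same numbers adjusted over the list alone; adjusted p = 0.749). The recombinase genes Rag1 (1.72 ± 0.25) and Rag2 (0.85 ± 0.09), the interleukin 7 receptor gene Il7r (1.02 ± 0.07) and the stem cell factor receptor gene Kit (1.60 ± 0.11) were higher. Without either wild type library the call of Rag1 was lost (adjusted p up to 0.0827).

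The called genes with the largest differences were led by the LIM homeobox gene Lhx2, at 0.3 RPKM in both wild type libraries and 54.4 and 47 RPKM in the ZnF1 mutant (5.31 ± 0.14). Next came Ccl8 (3.78 ± 0.40), Cd33 (3.77 ± 0.20), Htra3 (3.17 ± 0.16), the scavenger receptor Cd36 (3.09 ± 0.30), Hip1 (3.08 ± 0.09), Colec12 (3.04 ± 0.15), H2-M2 (2.98 ± 0.21) and lipoprotein lipase, Lpl (2.93 ± 0.20). Rps4y2 (3.88 ± 0.52) belongs to this group, but it resembles other ribosomal protein S4 sequences and its reads are uncertain. Among the largest falls were those of the small heat shock gene Hspb8 (-3.44 ± 0.18), Tmem59l (-3.19 ± 0.42), Fcrl6 (-3.07 ± 0.29), Fetub (-2.48 ± 0.26), the B cell chemokine receptor Cxcr5 (-2.46 ± 0.46), Rps6ka6 (-2.34 ± 0.26), Egln3 (-2.32 ± 0.10), Camk2b (-2.31 ± 0.12) and Grb7 (-2.31 ± 0.35). Calls were lost for Rps4y2 without the wild type library of day 28 or the ZnF1 library of day 21 (adjusted p up to 0.073). The call of Tmem59l was lost without the wild type library of day 21 (adjusted p = 0.0569). That of Grb7 was lost without either wild type library (adjusted p up to 0.0906). The call of Cxcr5 was lost without the ZnF1 library of day 21, without either ZnF4 library and without the filter (adjusted p up to 0.113 with 1 library left out).

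By the limma test 4336 of 11379 genes were called in this comparison, 2606 higher and 1730 lower. At least 2-fold, 1113 were higher and 66 lower. Of these higher genes, 358 were below 1 RPKM in both wild type libraries and so passed the filter only through mutant libraries. Of the lower genes, 24 were below 1 RPKM in both ZnF1 libraries. Without a test, 936 genes were 2-fold higher and 52 lower on both days, and the differences of the 2 days correlated at 0.911 across genes. These 2-fold counts were 607 higher and 104 lower with quantile scaling, and 1392 and 92 with a pseudocount of 0.1. The count fell to 1659 and 1398 without the wild type library of day 21 and day 28, and to 1670 and 1770 without the ZnF1 library of day 21 and day 28. In the same order, the higher genes went to 1516, 1266, 1522 and 1465, and the lower genes to 143, 132, 148 and 305. Quantile scaling turned the split, with 2047 higher and 2913 lower genes, as did a mean RPKM of at least 4, with 1406 higher and 1550 lower.

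In the ZnF4 mutant, the imprinted growth genes H19 and Igf2, the receptor gene Kit and most glycolysis genes were higher than in wild type. Most tested p53 target genes were lower, and neither list passed with an estimated correlation. H19, a non-coding RNA, had 12.2 and 1.3 RPKM in wild type and 3062.2 and 2008.3 RPKM in the ZnF4 mutant (8.82 ± 0.69, adjusted p = 0.00194), a call lost without either ZnF4 library (adjusted p up to 0.0648). Its neighbour Igf2, insulin-like growth factor 2, had 0.7 and 0.2 RPKM in wild type and 247.2 and 175.2 RPKM in the ZnF4 mutant (7.19 ± 0.14, adjusted p = 0.000288). Kit rose from 0.1 RPKM or below to 17.4 and 12.5 RPKM (3.91 ± 0.11). The homeobox gene Hoxb7 was listed at 0 in both wild type libraries and had 18.6 and 11.4 RPKM in the ZnF4 mutant, and the T cell leukaemia oncogene Lmo1, also listed at 0, had 9.7 and 12.3 RPKM. Other leading genes were Ndrg1 (3.70 ± 0.15), Prdm8 (3.59 ± 0.14), Efna1 (3.44 ± 0.25), the collagen chaperone Serpinh1 (3.43 ± 0.39) and the water channel Aqp1 (3.41 ± 0.11). Rag1 (2.08 ± 0.25), Rag2 (0.9975 ± 0.09), Ccnd1 (2.41 ± 0.09), Ptk2 (2.87 ± 0.13) and Ctnnd1 (1.80 ± 0.07) were higher as well. The V(D)J recombination list did not pass (2 of 12 higher, 3 lower, the same numbers adjusted over the list alone; adjusted p = 0.91). The adhesion list did not pass either (9 of 22 higher, 3 lower; 10 and 3 adjusted over the list alone; adjusted p = 0.0718). Calls were lost for Rag1 without any 1 of the wild type or ZnF4 libraries (adjusted p up to 0.0987). Rag2 was not called without the wild type library of day 21 or either ZnF4 library (adjusted p up to 0.057). Serpinh1 was not called without the wild type library of day 28 (adjusted p = 0.0663). Rag1 and Serpinh1 were not called without the filter either.

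Glycolysis and glucose transport genes were higher in 11 of 15 cases and lower in 0 (12 adjusted over the list alone; median 0.55). They included the phosphofructokinase genes Pfkl (1.005 ± 0.07) and Pfkp (0.74 ± 0.09), Aldoa (0.93 ± 0.09) and the glucose transporter Slc2a1 (0.75 ± 0.07). The list passed at adjusted p = 5.24e-05, and had adjusted p = 0.603 with an estimated correlation. Proliferation genes shifted upwards as a list (median 0.21; adjusted p = 0.000427, and adjusted p = 0.603 with an estimated correlation), but only 2 of 24 were called singly (1 adjusted over the list alone), Aurkb (0.38 ± 0.06) and Bub1 (0.38 ± 0.08). Both calls were lost without any 1 of the 6 libraries, and that of Bub1 also without the filter (adjusted p = 0.083). The calls of Aldoa and Slc2a1 were lost without either wild type library (adjusted p up to 0.0743 and 0.0704). That of Pfkp was lost without any 1 of the wild type or ZnF4 libraries (adjusted p up to 0.0946).

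Of 16 tested p53 targets 10 were lower and 1 was higher (12 and 1 adjusted over the list alone; median -0.47). Among them were the cell cycle inhibitor Cdkn1a (-1.23 ± 0.10), Trp53inp1 (-1.15 ± 0.09), Zmat3 (-0.89 ± 0.09) and Ccng1 (-0.71 ± 0.08). The list passed at adjusted p = 4.56e-06, and had adjusted p = 0.603 with an estimated correlation. Calls were lost for Cdkn1a without either ZnF4 library (adjusted p up to 0.0596). Zmat3 was not called without either wild type library (adjusted p up to 0.0748), nor Trp53inp1 without the wild type library of day 28 (adjusted p = 0.0563). Ccng1 was not called without either wild type library or the ZnF4 library of day 28 (adjusted p up to 0.104). Cdkn2a, which encodes the inhibitors Ink4a and Arf, was lower (-1.19 ± 0.11), from 25.2 and 40.2 RPKM to 10.4 and 17.3 RPKM. This call was lost without the block on day and without any 1 of the wild type or ZnF4 libraries (adjusted p up to 0.0635). Its list of cyclin-dependent kinase inhibitors and D cyclins passed narrowly (1 of 10 higher, 3 lower; 1 and 5 adjusted over the list alone; median -0.28; adjusted p = 0.0456, and adjusted p = 0.603 with an estimated correlation). That call was lost without the block, without the filter, under both other scalings, with a pseudocount of 0.1, and without the wild type or ZnF4 library of day 28 or either ZnF1 library (adjusted p up to 0.22).

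B cell transcription factors were lower in 4 of 20 cases and higher in 1 (6 and 1 adjusted over the list alone; median -0.32; adjusted p = 0.00864, and adjusted p = 0.603 with an estimated correlation). These were Bach2 (-1.02 ± 0.07), Pou2f2 (-0.77 ± 0.09), Pou2af1 (-0.65 ± 0.09) and Spib (-1.43 ± 0.21), while Pax5 (0.11 ± 0.09) and Ebf1 (-0.06 ± 0.09) were not called. The list's call was lost without the wild type or the ZnF4 library of day 21 (medians -0.11 and -0.16; adjusted p up to 0.193). The calls of Pou2f2, Pou2af1 and Spib were lost without any 1 of the wild type or ZnF4 libraries (adjusted p up to 0.0926, 0.163 and 0.15). The pre-B cell receptor list did not pass (4 of 19 higher, 5 lower; 5 and 5 adjusted over the list alone; median -0.08; adjusted p = 0.442). Within it the kinase Blk (-3.15 ± 0.43) and the adaptor Dok3 (-2.27 ± 0.26) were lower and Cd22 (1.005 ± 0.13) was higher. Igll1 was higher by 0.54 ± 0.11 (adjusted p = 0.0303), a call lost without any 1 of the 6 libraries (adjusted p up to 0.316), without the block on day, without the filter and with quantile scaling. Vpreb1 (-0.07 ± 0.17) and Il7r (-0.15 ± 0.07) were not called. Dntt, the terminal transferase of pro-B cells, was lower (-2.06 ± 0.21). Calls were lost for Blk and Dntt without either wild type library (adjusted p up to 0.129 and 0.071). Dok3 was not called without either wild type library or the ZnF4 library of day 28 (adjusted p up to 0.0958), nor Cd22 without the wild type library of day 28 or either ZnF4 library (adjusted p up to 0.0928). None of these 4 genes was called without the filter, and Cd22 was not called without the block on day either (adjusted p = 0.1035).

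Of later B cell genes 7 of 21 were lower and 2 higher, the same numbers adjusted over the list alone (median -0.21; adjusted p = 0.0456, and adjusted p = 0.603 with an estimated correlation), with Il2ra (-3.53 ± 0.23), Cd74 (-2.39 ± 0.18) and Cd2 (-1.94 ± 0.15) among the lower. STAT5 and cytokine targets were lower in 7 of 20 cases and higher in 2 (9 and 4 adjusted over the list alone; median -0.09; adjusted p = 0.0404, and adjusted p = 0.603 with an estimated correlation), with Socs1 at -1.80 ± 0.12 and Pim1 at -1.05 ± 0.09. Myeloid markers were lower in 5 of 14 cases (7 adjusted over the list alone; median -0.71; adjusted p = 0.000181, and adjusted p = 0.603 with an estimated correlation). Stromal markers were lower in 5 of 15 (5 adjusted over the list alone; median -0.53; adjusted p = 0.00783, and adjusted p = 0.725 with an estimated correlation). Interferon-stimulated genes were lower in 4 of 16 and higher in 1, the same numbers adjusted over the list alone (median -0.33; adjusted p = 0.00883, and adjusted p = 0.725 with an estimated correlation), with Gbp2 at -2.79 ± 0.20. List calls were lost for later B cell genes and STAT5 targets without either ZnF1 or either ZnF4 library and under both other scalings (adjusted p up to 0.139 and 0.0782). That of later B cell genes was also lost with a pseudocount of 0.1 (adjusted p = 0.0853) and without the filter (median 0; adjusted p = 0.208). The STAT5 call was also lost without the wild type library of day 21 and without the block. The interferon call was lost without the wild type library of day 21, the ZnF4 library of day 28 or the filter (medians -0.06, -0.25 and -0.28; adjusted p up to 0.112). The stromal call was lost without the ZnF4 library of day 21 or the filter (medians -0.45 and -0.17; adjusted p up to 0.246). Among single genes, Cd74 was not called without either ZnF4 library (adjusted p up to 0.0576). Cd2 was not called without the wild type library of day 28 (adjusted p = 0.0521), nor Pim1 without that library or either ZnF4 library (adjusted p up to 0.0609).

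Among the largest called falls in the ZnF4 mutant were the lymphoid surface gene Ly6d (-4.90 ± 0.23), Fcrl6 (-4.86 ± 0.29), the glycine decarboxylase gene Gldc (-4.84 ± 0.32), the pre-B cell antigen gene Enpep (-4.21 ± 0.67), Tmem59l (-4.18 ± 0.42), Cdhr2 (-4.14 ± 0.31), Il2ra, Arl5c (-3.45 ± 0.30) and Prkcq (-3.37 ± 0.15). Ly6d went from 107.2 and 110.1 RPKM to 2.2 and 3.2 RPKM. Calls were lost for Enpep without any 1 of the wild type or ZnF4 libraries (adjusted p up to 0.155). Tmem59l was not called without the wild type library of day 21 or either ZnF4 library (adjusted p up to 0.0804), nor Cdhr2 and Arl5c without the wild type library of day 28 (adjusted p = 0.0502 and 0.0538).

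The limma test called 2076 of 11379 genes for the ZnF4 mutant, 1243 higher and 833 lower, and of these 364 were at least 2-fold higher and 256 lower. Among these 2-fold calls, 118 higher genes were below 1 RPKM in both wild type libraries and 65 lower genes in both ZnF4 libraries. On both days 290 genes were 2-fold higher and 203 lower, and the differences of the days correlated at 0.853 across genes. With a pseudocount of 0.1, 458 genes were 2-fold higher and 330 lower on both days. At a mean RPKM of at least 4 these were 160 and 152. The limma count was 1230 and 1222 without the ZnF1 library of day 21 and day 28, and 1137 without the filter. It was lower still without any 1 of the wild type or ZnF4 libraries.

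**Figure D2:**
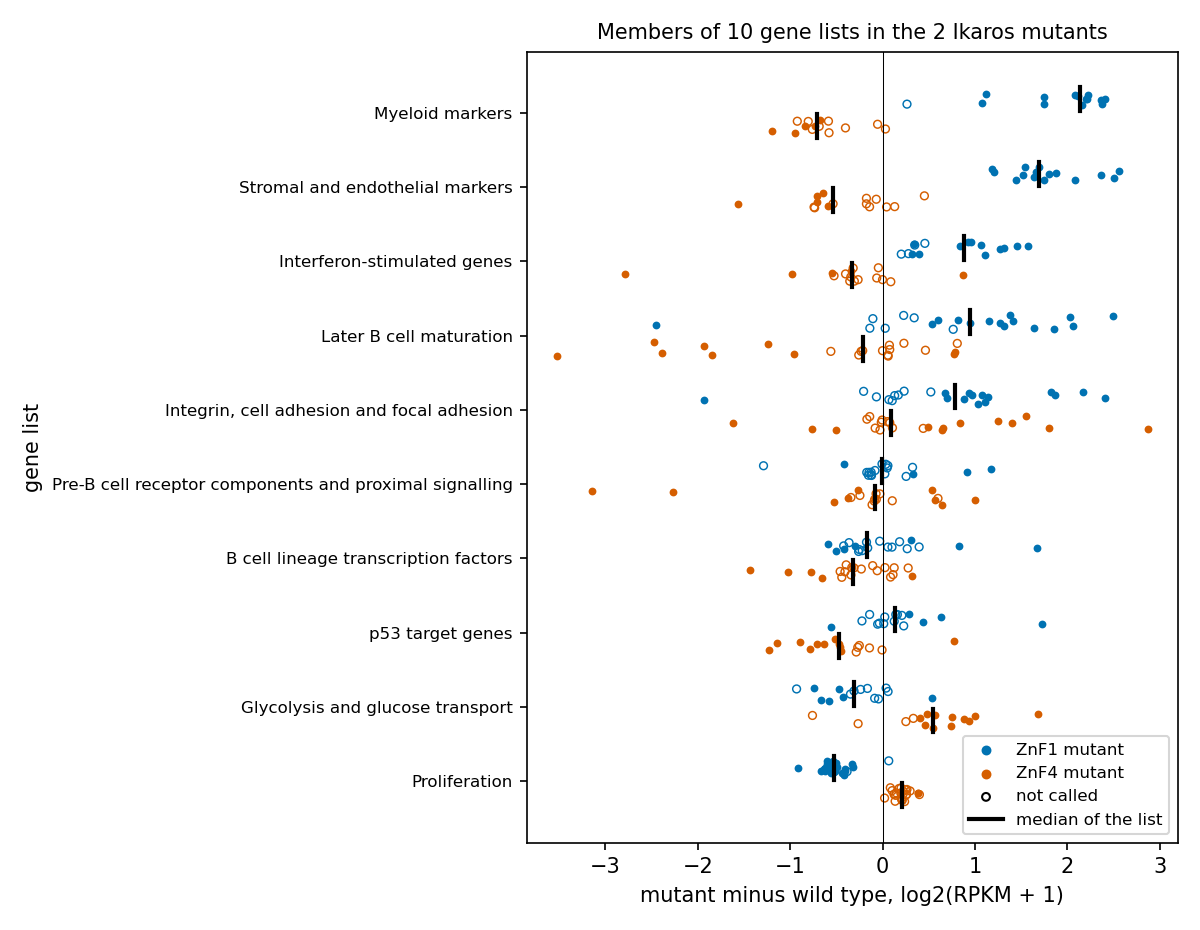
Difference from wild type on the log2(RPKM + 1) scale for each tested member of 10 gene lists, blue for the ZnF1 mutant and orange for the ZnF4 mutant; filled points were called, open points were not, and black bars are list medians. Myeloid markers had a median of 2.135 in the ZnF1 mutant and -0.71 in the ZnF4 mutant, and proliferation genes -0.52 and 0.21.

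Set against each other, the 2 mutants differed in myeloid, stromal, interferon-stimulated and later B cell transcripts, which were lower in the ZnF4 mutant, and in proliferation and glycolysis transcripts, which were higher. All 14 tested myeloid markers (median -2.88; adjusted p = 3.85e-08, and adjusted p = 0.347 with an estimated correlation) and all 15 tested stromal markers (median -2.29; adjusted p = 1.95e-08, and adjusted p = 0.347 with an estimated correlation) were lower, 14 and 15 of them adjusted over the list alone. Csf1r, the receptor of macrophage colony-stimulating factor, was lower (-3.06 ± 0.21), as was Bgn (-3.21 ± 0.12). Interferon-stimulated genes were lower in 13 of 16 cases (14 adjusted over the list alone; median -1.22; adjusted p = 1.02e-05, and adjusted p = 0.389 with an estimated correlation) and later B cell genes in 13 of 21 (14 adjusted over the list alone; median -1.39; adjusted p = 9.82e-05, and adjusted p = 0.347 with an estimated correlation).

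Proliferation genes were higher in the ZnF4 mutant than in the ZnF1 mutant in 23 of 24 cases (24 adjusted over the list alone; median 0.74; adjusted p = 5.06e-09, and adjusted p = 0.347 with an estimated correlation). Glycolysis genes were higher in 11 of 15 (11 adjusted over the list alone; median 0.98; adjusted p = 4.48e-05, and adjusted p = 0.347 with an estimated correlation), and NuRD subunits in 8 of 13 (8 adjusted over the list alone; median 0.39; adjusted p = 0.00516, and adjusted p = 0.347 with an estimated correlation). The NuRD call was lost with quantile scaling (adjusted p = 0.0549). Of p53 targets 14 of 16 were lower and 2 higher, the same numbers adjusted over the list alone (median -0.57; adjusted p = 0.000218, and adjusted p = 0.347 with an estimated correlation), with Plk2 at -2.36 ± 0.11 and Cdkn1a at -1.38 ± 0.10. STAT5 and cytokine targets were lower in 13 of 20 and higher in 2, the same numbers adjusted over the list alone (median -0.44; adjusted p = 0.00488, and adjusted p = 0.347 with an estimated correlation), with Socs1 at -2.41 ± 0.12 and Bcl6 at -1.71 ± 0.15. Cyclin-dependent kinase inhibitors and D cyclins were lower in 5 of 10, 5 also adjusted over the list alone (median -0.37; adjusted p = 0.0138, and adjusted p = 0.347 with an estimated correlation), a call lost without the block on day (adjusted p = 0.0525).

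Single genes that were higher in the ZnF4 mutant than in the ZnF1 mutant were led by H19 (6.36 ± 0.69), Igf2 (4.90 ± 0.14), Fetub (4.07 ± 0.26), the troponin gene Tnni2 (3.85 ± 0.18), Ndrg1 (3.61 ± 0.15), Tac4 (3.53 ± 0.16), Prdm8 (3.15 ± 0.14), Rbpms (3.02 ± 0.12) and Tubb3 (2.96 ± 0.43). Igf2as, an antisense transcript that overlaps Igf2, was listed at 0 in wild type, at 0 and 0.2 RPKM in the ZnF1 mutant and at 9.7 and 7.9 RPKM in the ZnF4 mutant, and its reads cannot be told from those of Igf2 without a strand. The lower genes were led by Cd74 (-4.42 ± 0.18), Nov (-4.32 ± 0.08), the gap junction gene Gja1 (-4.28 ± 0.38), Cd33 (-4.13 ± 0.20), Apoe (-3.99 ± 0.18), Gldc (-3.93 ± 0.32), Il2ra (-3.87 ± 0.23), Arl5c (-3.80 ± 0.30) and Enpep (-3.77 ± 0.67). Kit was higher by 2.31 ± 0.11 and Il7r lower (-1.17 ± 0.07), and Ikzf1 was higher by 0.82 ± 0.07. Ikzf3 (-0.02 ± 0.08), Vpreb1 (0.05 ± 0.17) and Rag1 (0.36 ± 0.25) were not called. The calls of Tubb3 and Enpep were lost without either ZnF4 library (adjusted p up to 0.0685 and 0.106). In all 5177 of 11379 genes were called by limma, 2540 higher and 2637 lower, and 186 were 2-fold higher and 999 lower on both days (273 and 740 with quantile scaling). The count was 2526 (752 higher, 1774 lower) and 2632 (958 higher, 1674 lower) without the ZnF1 library of day 21 and day 28. Quantile scaling moved the split to 3431 higher and 2359 lower, and median-of-ratios scaling the other way, to 2038 higher and 2968 lower.

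Many genes were called in the same direction in both mutants. Of genes called in both, 581 genes were higher in each mutant and 213 lower in each, against 284.7 and 126.6 for independent lists. Simulated unchanged mutants gave 0.05 and 0.02 on average. Without any change almost nothing is called, so these simulated values were fixed in advance and do not bear on sharing. A further 397 genes went in opposite directions, against 379.8 for independent lists. The 2 sets of differences had a covariance across genes of 0.056, against 0.0073 simulated. Their correlation of 0.174 lay below the 0.501 simulated for unchanged mutants, which differ from the shared wild type libraries by chance alone. The shared controls alone give that simulated value, so this comparison does not decide whether the mutants share changes. With 1 wild type library per day the controls could not be split, and part of the excess may come from the shared controls. Both comparisons also use the same variance estimate for each gene, which can add to the excess. At least 2-fold in both mutants, 148 genes were higher and 32 lower. The higher genes included Lhx2 (3.36 ± 0.14 in the ZnF4 mutant), Hip1, Ccnd1, Kit, Igf2 and Rag1, and the lower genes included Fcrl6, Cxcr5, Tmem59l, Camk2b and Rps6ka6. In total 794 genes were called in the same direction in both, against 201 and 134 without the wild type library of day 21 and day 28, 318 and 346 without the ZnF1 library of day 21 and day 28, and 332 and 201 without the ZnF4 library of day 21 and day 28. Without the filter there were 477, and 505 at a mean RPKM of at least 4.

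**Figure D3:**
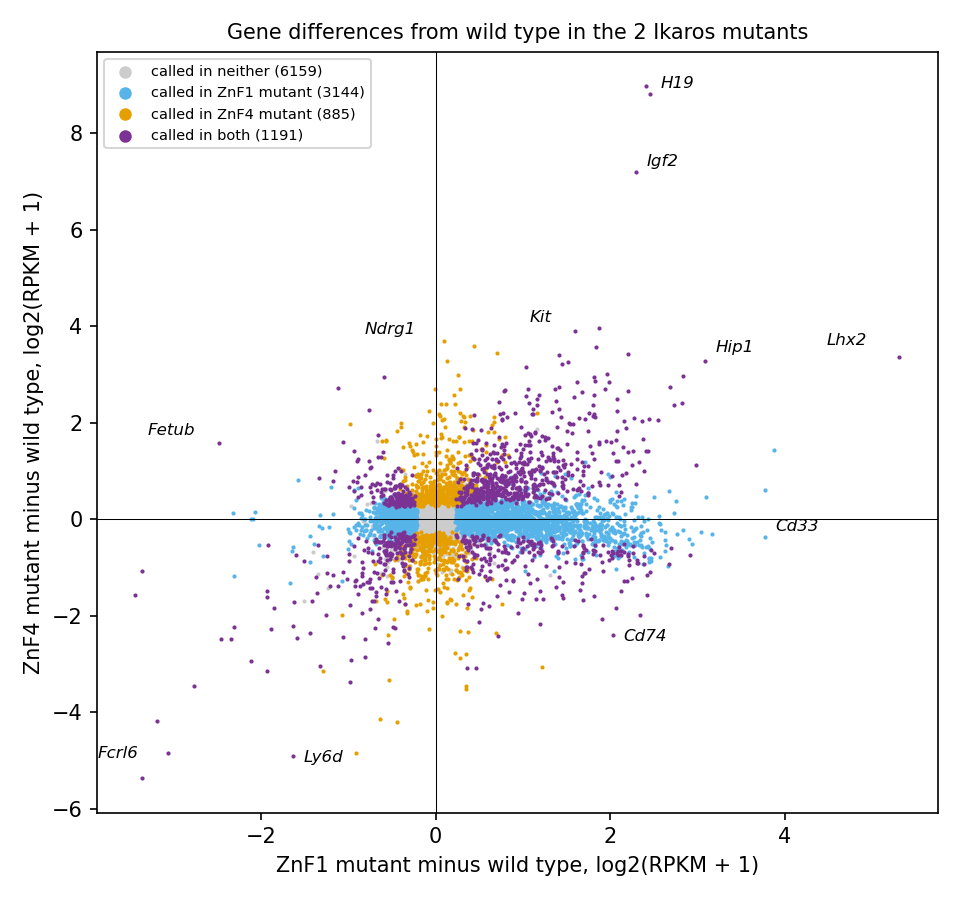
Difference from wild type of 11379 genes in the ZnF1 mutant (x axis) and the ZnF4 mutant (y axis) on the log2(RPKM + 1) scale, 1 point per gene, coloured by the comparisons in which the gene was called. H19 and Igf2 stand at 8.82 and 7.19 on the y axis, and Lhx2 at 5.31 on the x axis. The correlation was 0.174, against 0.501 for simulated unchanged mutants that share the wild type libraries. The shared libraries alone give that simulated value, so it does not decide whether changes are shared.

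Between day 21 and day 28 no gene passed the test. Scand1 went from 3.0, 1.9 and 1.7 RPKM at day 21 to 10.9, 19.6 and 10.5 RPKM at day 28 in wild type, ZnF1 and ZnF4 libraries, and the mitochondrial gene Romo1 from 15.1, 9.3 and 11.9 to 32.2, 32.1 and 35.2 RPKM. The ribosomal stalk gene Rplp1 (167.1, 125.6 and 129.9 to 291.3, 277.9 and 427.7 RPKM) and cyclin D2, Ccnd2 (42.9, 59.0 and 24.2 to 73.3, 95.2 and 62.2 RPKM), had higher values at day 28 in each genotype. Fxyd6 went from 2.5, 13.2 and 30.8 to 1.1, 6.9 and 13.9 RPKM, and Cd22 from 5.3, 4.0 and 10.1 to 2.5, 2.6 and 7.0 RPKM. Lists of p53 targets (median 0.12; adjusted p = 0.00671) and STAT5 and cytokine targets (median 0.15; adjusted p = 0.0302) had higher values and stromal markers (median -0.18; adjusted p = 0.0302) lower values at day 28, and adjusted p was 0.743, 0.743 and 0.744 with an estimated correlation. Limma called 0 of 11379 genes for day (1631 at an unadjusted p below 0.05, smallest adjusted p = 0.154). Shorter transcripts had higher values at day 28: the difference correlated with transcript length across genes (Spearman -0.352; -0.258, -0.391 and -0.12 in the wild type, ZnF1 and ZnF4 libraries).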

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

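All tests of explanations in this part were chosen after the results were seen. Several gene lists moved in opposite directions in the 2 mutants and also differed between them in the direct limma comparison. As ZnF4 mutant minus ZnF1 mutant, the list medians were -2.88 for myeloid markers, -2.29 for stromal markers, -1.39 for later B cell genes, -1.22 for interferon-stimulated genes, 0.74 for proliferation genes and 0.98 for glycolysis genes. With an estimated correlation these list tests had an adjusted p of 0.389 for interferon-stimulated genes and 0.347 for the others, and 3 of the calls in the ZnF4 mutant were lost under other settings. Later B cell genes lost theirs under both other scalings, with a pseudocount of 0.1, without the filter (median 0; adjusted p = 0.208) and without either ZnF1 or either ZnF4 library. Interferon-stimulated genes lost theirs without the wild type library of day 21 (median -0.06; adjusted p = 0.112), the ZnF4 library of day 28 or the filter, and stromal markers without the ZnF4 library of day 21 (adjusted p = 0.246) or the filter. Single named genes with the same behaviour were Fetub (4.07), Tnni2 (3.85), Tac4 (3.53), Rbpms (3.02), Cd74 (-4.42), Nov (-4.32) and Apoe (-3.99). Lat, an adaptor of T cell receptor signalling chosen after its values were seen, was 2-fold higher in the ZnF4 than in the ZnF1 mutant at day 21 (1.09) and 2-fold lower at day 28 (-1.46), a change of -2.55 that was not tested.

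The rise of macrophage and stromal transcripts in the ZnF1 mutant was weighed first. More macrophages in the ZnF1 cultures stay open as a source of the myeloid part: 92.9% of the tested members of the myeloid list were higher, with Lyz2 (chosen after its values were seen) at 263.8 and 166.7 RPKM in wild type and 927.8 and 893.5 RPKM in the ZnF1 mutant, but this list is the pattern itself and decides nothing. Dilution of the B-lineage cells as the whole cause of the lower proliferation transcripts is argued against by 10 B-lineage restricted transcripts. Their list was written after the leading genes had been seen. Its median difference was 0.00967 ± 0.20 (SD over genes), against -0.52 for the proliferation list. Of the lists written beforehand, B cell transcription factors had a median of -0.17 (3 of 20 higher, 4 lower, camera adjusted p = 0.57). The pre-B cell receptor list had a median of -0.01. A smaller part played by dilution was not tested. The same myeloid and stromal lists differed by -0.43 and -0.43 between the 2 wild type days, so they also varied within a genotype. An effect of the genotype and a feature of a single culture cannot be told apart with 2 libraries per genotype that are not known to be separate cultures.

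The high values of H19 and Igf2 in the ZnF4 mutant were weighed next. Stromal cells as a source are argued against by the stromal list, whose median was -0.53 in the ZnF4 mutant with 0 members higher. The median stayed negative without the ZnF4 library of day 21 (-0.45) and without the filter (-0.17), where the list's call was lost. In the ZnF1 mutant, where the stromal list was higher, H19 (2.46 ± 0.69; limma adjusted p = 0.0422) and Igf2 (2.29) were called higher too. The H19 difference there was uneven, 0.904 at day 21 and 4.008 at day 28, with 12.2 and 1.3 RPKM in wild type. A stromal source of the H19 and Igf2 values in the ZnF1 mutant was not tested. Mir675, a microRNA inside H19 chosen after its values were seen, had 2676 and 1575.9 RPKM in the ZnF4 mutant; its ratio to H19 varied only 1.64-fold over the 6 libraries while H19 varied 2356-fold, in line with H19 reads counted for Mir675. H19 took 0.964% and 0.623% of the length-weighted RPKM sum in the ZnF4 libraries. Whether the rise belongs to the genotype or arose in 1 culture cannot be told apart with 2 libraries per genotype.

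The lower p53 targets and Cdkn2a in the ZnF4 mutant were weighed last. If fewer macrophages were the cause, the targets should be higher in the ZnF1 mutant by at least the size of their change in the ZnF4 mutant (-0.47). Their median there was 0.14 with an SD over genes of 0.49, which leaves the question open for the targets. For Cdkn2a it is argued against, since its difference in the ZnF1 mutant was -0.12 ± 0.11 (SE), against -1.19 in the ZnF4 mutant. Genotype and culture cannot be told apart here either with 2 libraries per genotype.

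For the comparison of days, 10 of the 10 splits of the 6 libraries into 3 and 3 gave as many called genes as the real one, which called 0, and the highest other split called 0. With a real count of 0 every split does so, and so few splits cannot give a share below 0.05.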

How the results depend on the processing

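No called named gene or list changed direction with a pseudocount of 0.1, without the filter or the block, under either other scaling or with 1 library left out; other settings were run for counts only. The counts for the ZnF1 mutant, the ZnF4 mutant and their direct comparison were 4336, 2076 and 5177, and 3653, 1687 and 4632 without the block on day, so the block moved none of them by over 1.5 times; 19 calls of named genes and 3 list calls were lost without it, and 26 lists passed in all. With 1 library left out they ranged from 1398 to 4475, from 346 to 1230 and from 2526 to 3896, the left-out genotype's remaining library being assumed to vary like the others. Without the filter the ZnF4 count was 1137 and the shared count 477, and without the ZnF1 libraries, an alternative chosen after seeing the data, the ZnF4 count was 1231. The cause was not tested. The genes 2-fold apart on both days (988, 493 and 1185) became 1484, 788 and 1602 with a pseudocount of 0.1, and 491, 312 and 593 at a mean RPKM of at least 4, where fewer genes enter. With quantile scaling they were 607 higher and 104 lower, 252 and 197, and 273 and 740. The number of genes called in the same direction in both mutants was 794, against 505 at that mean RPKM and 134 to 346 with 1 library left out. Quantile scaling moved the share of higher calls from 60.1% to 41.3% in the ZnF1 mutant and from 49.1% to 59.3% between the mutants, where the median of all genes went to -0.12 and 0.12. Median-of-ratios scaling gave 67.0% and 40.7%, no filter 71.2% and 39.5%, and a mean RPKM of at least 4 gave 47.6% and 58.5%. Of 28 list calls 0 held with an estimated correlation. With the preset one, 23 to 26 of them held under the other settings with all libraries, and with 1 library left out 149 list calls held and 19 were lost, summed over the libraries. The calls lost most often were those of later B cell genes, STAT5 targets and cyclin-dependent kinase inhibitors in the ZnF4 mutant. Of 282 calls of named genes 169 held with any 1 library left out, and 113 were lost at least once: 39 of 101 in the ZnF1 mutant (adjusted p up to 0.285), 58 of 83 in the ZnF4 mutant (up to 0.316) and 16 of 98 between the mutants (up to 0.245). They include Rag1, Ikzf3, Cdkn1a, Cdkn2a, Blk, Dntt, Cd74, Enpep and Tmem59l in the ZnF4 mutant and Rag1, Mki67, Ikzf3, Cxcr5, Grb7, Rps4y2 and Tmem59l in the ZnF1 mutant. With 1 library left out the fit has fewer residual degrees of freedom, so a call can be lost with its estimate unchanged. Cxcr5 in the ZnF1 mutant, for example, stayed at -2.46 without either ZnF4 library. A lost call therefore does not show that a difference hangs on that library. No count changed by over 1.5 times with rows under 300 bases and non-coding rows left out or with the length trend removed, both chosen after seeing the data. The day comparison called 0 genes under every setting. Read depth is unknown, so the precision of low values is too.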

Other observations

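The lists in this part were written after the leading genes had been seen, and its single genes were chosen after their values were seen. Cytosolic aminoacyl-tRNA synthetase genes, which charge tRNAs with amino acids, were lower in 17 of 20 cases in the ZnF1 mutant (median -0.36) and higher in 11 of 20 in the ZnF4 mutant (median 0.32); adjusted p was 6.53e-07 and 0.000392 by camera, and adjusted p = 0.347 and adjusted p = 0.495 with an estimated correlation. Asns, asparagine synthetase, had 36.3 and 74.9 RPKM in wild type, 19.8 and 36.3 in the ZnF1 mutant and 125.4 and 157.6 in the ZnF4 mutant. Cholesterol synthesis genes had medians of -0.33 and 0.31, with 8 of 18 lower and 1 higher in the ZnF1 mutant and 4 higher in the ZnF4 mutant (adjusted p = 0.00415 and 0.00155, and adjusted p = 0.618 and adjusted p = 0.498 with an estimated correlation). Ribosomal protein genes had a median of -0.13 in the ZnF1 mutant, with 3 of 77 called lower and 1 higher (adjusted p = 0.00424, and adjusted p = 0.718 with an estimated correlation). Their median was -0.07 in the ZnF4 mutant (adjusted p = 0.146). Between the days aminoacyl-tRNA synthetase and ribosomal protein genes also passed, with higher values at day 28 (medians 0.16 and 0.15). Adjusted p was 6.59e-06 and 0.000278 by camera, and 0.698 and 0.803 with an estimated correlation. Over all tested genes, the median day difference was 0.19 for transcripts up to 500 bases and 0.14 from 500 to 1000 bases. It was -0.03 above 4000 bases. The list tests were not adjusted for transcript length.

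Of 8 tested Hox genes, 7 were higher in the ZnF1 mutant and 5 in the ZnF4 mutant (medians 0.71 and 1.16; adjusted p = 0.00113 and 0.000273, and adjusted p = 0.347 and adjusted p = 0.495 with an estimated correlation). In the ZnF4 mutant these were genes of the Hoxb cluster: Hoxb7 (18.6 and 11.4 RPKM, listed at 0 in wild type), Hoxb8 (2.99), Hoxb6 (2.49), Hoxb5 (1.46) and Hoxb3 (0.86). The Hox list was drawn only from genes that had passed the filter, with Hoxb7 already seen as a leading gene. A Hox gene silent in wild type could enter it only through mutant libraries. The shares and p-values of this list were thus partly fixed by selection and do not count as a test. Hypoxia response genes were higher in 7 of 18 cases in the ZnF4 mutant and lower in 0 (median 0.415; adjusted p = 0.000266, and adjusted p = 0.495 with an estimated correlation), with Ndrg1, Efna1, Bhlhe40 (1.58) and P4ha2 (1.39) leading, while Car9 (0.10) and Pdk1 (-0.01) were not called. Of 10 tested imprinted genes 6 were higher and 0 lower in the ZnF1 mutant (median 0.66; adjusted p = 0.00577, and adjusted p = 0.347 with an estimated correlation). In the ZnF4 mutant 4 were higher and 1 lower (median 0.13; adjusted p = 0.0333, and adjusted p = 0.495 with an estimated correlation), among them Grb10 (2.85) beside H19 and Igf2, and Mest (0.12) was not called. Between the mutants this list did not pass (adjusted p = 0.869). The imprinted list holds H19 and Igf2, and the hypoxia list Ndrg1 and Efna1, all leading genes seen before the lists were written. The p-values of these 2 lists in the ZnF4 mutant therefore partly restate those genes. Of 10 B-lineage restricted transcripts 2 were higher and 0 lower in the ZnF4 mutant (median -0.07; adjusted p = 0.752). Among 34 tested macrophage transcripts 33 were higher in the ZnF1 mutant (median 2.20; adjusted p = 9.79e-15, and adjusted p = 0.347 with an estimated correlation), such as Lyz2 at 263.8 and 166.7 RPKM in wild type and 927.8 and 893.5 RPKM in the ZnF1 mutant. Between the days they were lower at day 28 (median -0.09; adjusted p = 0.00491, and adjusted p = 0.803 with an estimated correlation). Y-linked Ddx3y had 13.0 to 16.5 RPKM over the 6 libraries and Kdm5d 9.1 to 10.8 RPKM. Y-linked Eif2s3y had 23 and 10.6 RPKM in wild type, 36.5 RPKM in both ZnF1 libraries, and 42.1 and 35.5 RPKM in the ZnF4 mutant. It was called higher in both mutants (1.17 ± 0.25 and 1.25 ± 0.25; adjusted p = 0.0192 and 0.0275). Both calls were lost without the filter and without any 1 library other than the wild type library of day 21 (adjusted p up to 0.139 and 0.203), and that in the ZnF4 mutant was also lost without the block on day.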
